A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

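Gene expression was measured in 12 fixed-cell suspensions (6 tumours in 2 fractions) with Parse Evercode WT v2, a combinatorial barcoding method in which each sample is marked by its first-round wells, 2 per sample, and transcripts are counted by unique molecular identifiers (UMIs). Per the labels, cells were divided over 8 sublibraries, 4 of which were sequenced again for depth, and the reads were demultiplexed with split-pipe 1.0.6p in a single run holding all samples. Per the submitters' processing notes, STAR and Scanpy were used, without versions, and the builds GRCh38, GRCm39 and hg38 were named. The deposited matrices hold whole-number UMI counts per cell and gene, which the authors had not normalised. Tumour-fraction matrices list 62710 human genes and the myeloid ones 57010 mouse genes, and each cell carries 1 species tag per fraction, so that human and mouse reads of one cell cannot be compared. How cells were called and assigned to a species, and whether counting used strand, is not given in the sources used here.

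Groups and mouse numbers came from the labels, with 3 libraries in each of 4 groups. Same-numbered libraries came from the same mouse, as the study design states, so the mouse was a term of the model. Deviations of partner libraries from their group means correlated across genes at -0.041, 0.222 and -0.086 in the tumour fraction and at 0.016, 0.236 and 0.102 in the myeloid fraction. Every pair of libraries differed by more than sampling noise (chi-square per gene of at least 14.6), so none was counted as a repeat. Total counts per library ran from 43122806 to 266689908 UMIs in the tumour fraction and from 1704039 to 5664489 in the myeloid fraction.

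Counts of all deposited cells were summed per library, since cells are not replicates. edgeR 4.0.16 in R 4.3.3 fitted mouse and group by quasi-likelihood (glmQLFit with the robust option and glmQLFTest) after filterByExpr and TMM normalisation, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors were taken from the fold change and the test statistic. Normalised values are CPM with TMM library sizes. Lists of genes and of cell type markers were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, two-sided, for lists with at least 3 tested genes and adjusted over the lists of a species. Of 33 human lists all were tested, and of 35 mouse lists 26. The model, the lists, the markers and the rule for named genes were fixed before the data were examined.

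Genes were named in each fraction by a rule with 4 parts. The first took LOX and LOXL1 to LOXL4. The second took up to 7 rises and 7 falls among genes past the threshold with the same sign in 3 mice and a mean of at least 10 CPM. The next took the 3 members with the smallest p of each list past its threshold, for at most 8 lists; 2 members so taken are not reported here, and no others were taken in their place. The last filled each direction up to 5 by the smallest unadjusted p among genes with the same sign in 3 mice. Clone-based and LINC names, pseudogenes, antisense genes and genes without a symbol were left out of the second and last parts. In the tumour fraction the genes it added had passed the threshold but not the CPM minimum, and in the myeloid fraction none had passed. Coordinates are 1-based on GRCh38 from GENCODE release 29, matched by gene ID for 58274 of the 62710 human genes (92.9%).

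Cells were clustered per fraction with scanpy 1.11.5 and igraph 0.11.9 (scaling to 10000 counts per cell, logarithm, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). Values were rounded to 3 decimals and genes seen in fewer than 20 cells were left out, so that the partition does not depend on the processor. A cluster was named from the fixed markers where at least 3 of a class were found in at least 5% of its cells at 2 times the level of other cells and at least 1 was among its 10 leading genes. These thresholds were set after a first look at the data. Clustering was run in several numerical forms whose partitions, and some names, differed; an earlier form named a macrophage-like cluster at resolution 1, and the final form was chosen for reproducibility before its group comparisons were seen. The names are therefore one possible reading. Shares of cells were compared within mice by exact sign-flip permutation tests, two-sided, whose smallest p is 0.25 with 3 mice. Cell cycle phases were scored with scanpy after thinning each cell to 3400 UMIs, the 20th percentile of the shallowest library rounded down. Shares of counts or cells in a library have 95% Wilson intervals, which cover counting error only.

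Doublets were sought with Scrublet in each library. It marked under 0.5% of cells in 4 of 6 tumour libraries and in 6 of 6 myeloid libraries, and in 1 tumour library it marked most cells, so it was taken not to have worked and no doublet was removed. In its place, the 5% of cells with the most UMIs in each library were left out as an alternative added after seeing the data. Other alternatives were no mouse term, DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, cells with at least 500 UMIs (tumour) or 200 UMIs (myeloid) and under 15% mitochondrial counts, thinning to the smallest total, each set of sublibraries, each mouse left out, an estimated correlation, and fry. The procedure was tested on counts simulated from the tumour libraries over 26677 genes, where it recovered 24.7% of genes changed 2-fold and 87.4% of those changed 4-fold, with 12 false among 130 calls and 1 call with no change. On 5040 genes simulated from the myeloid libraries it recovered 41.7% and 97.8%, with 15 false among 149 calls and 0 with no change.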

Results

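Single-cell RNA profiles were collected from xenografts of MCF10DCIS.com, a human basal-like breast line whose lesions resemble ductal carcinoma in situ. The GFP-reporting cells carried either the empty pLKO vector or pLKO with an shRNA against LOX, a secreted enzyme that cross-links collagen and elastin. On each decellularised breast matrix from aged mice 50000 cells were seeded, cultured for 12 days and implanted in Rag1-deficient mice, which lack T and B cells. Each of the 3 mice carried a pLKO tumour on the right flank and an shLOX tumour on the left, so flank and vector cannot be told apart. The mice were chosen from 9 by tumour growth. Tumours were taken at week 7 and parted with magnetic beads into a CD11b-negative (tumour) and a CD11b-positive (myeloid) fraction, giving 12 libraries in 4 groups of 3. The number of shRNA sequences and of transduced lines behind each group is not given in the sources used here, so the spread between libraries is described only as that between tumours.

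Tumour volume was 327 ± 39.8 mm3 for pLKO and 168 ± 68.3 mm3 for shLOX (mean ± SD, n = 3 each). It was lower on the shLOX side in 3 of 3 mice, at 336 against 134, 361 against 124 and 283 against 247 mm3 (exact sign-flip permutation test over the mice, two-sided, p = 0.25, the smallest that 3 mice allow). Choosing the mice by growth makes these volumes no unbiased estimate.

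The tumour libraries held 2835 to 5036 cells and 43122806 to 266689908 transcript counts (UMIs). The totals for mice 1, 2 and 3 were 78083258, 43122806 and 109369593 in pLKO and 124454578, 266689908 and 93653867 in shLOX. Median UMIs per cell ran from 7458 to 26077. The myeloid libraries were far shallower, with 1393 to 3961 cells, 1704039 to 5664489 UMIs and medians of 291 to 1672.5 UMIs per cell. Median genes per cell ran from 57 to 240.5 there, against 2994 to 6088 in the tumour libraries, so each myeloid barcode held little information. The myeloid totals were 1982138, 2026684 and 1943073 in pLKO and 5267960, 5664489 and 1704039 in shLOX, so the shLOX library was the deeper one in mice 1 and 2 and the shallower one in mouse 3.

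The first comparison asked whether the tumour cells expressing the shRNA held less LOX transcript. LOX (ENSG00000113083, chromosome 5, 122063195 to 122078360, GRCh38) was not lower in the libraries labelled shLOX. It stood at 45.7, 31.3 and 27.8 normalised CPM in the pLKO libraries of mice 1, 2 and 3 and at 25.2, 45.9 and 40.8 CPM in those labelled shLOX, from 3437, 1368 and 2989 counts against 3289, 12304 and 3758. The group means were 34.9 ± 9.49 and 37.3 ± 10.8 CPM (SD, n = 3 each), and LOX was lower in the library labelled shLOX in mouse 1 only. The fitted log2 fold change was 0.09 (SE 0.29, edgeR adjusted p = 0.956). It was 0.55 without mouse 1, -0.16 without mouse 2 and -0.16 without mouse 3. Every direction below is therefore one between libraries labelled shLOX and pLKO, in which the LOX transcript itself had no consistent direction.

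Among the other lysyl oxidases, LOXL4 had the largest fitted value, at 10.0 ± 5.28 CPM in pLKO and 25.7 ± 21.7 CPM in the libraries labelled shLOX. Its log2 fold change of 1.18 (SE 0.23) was positive in 3 of 3 mice and did not pass over all genes (edgeR adjusted p = 0.281), although 1 gene of this list of 5, LOXL4, passed when adjusted over the list alone. The fitted values of LOXL1, LOXL2 and LOXL3 were -0.42, -0.12 and 0.29 (SE 0.44, 0.22 and 0.50). The family as a list did not pass (camera adjusted p = 0.650).

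**Figure D1:**
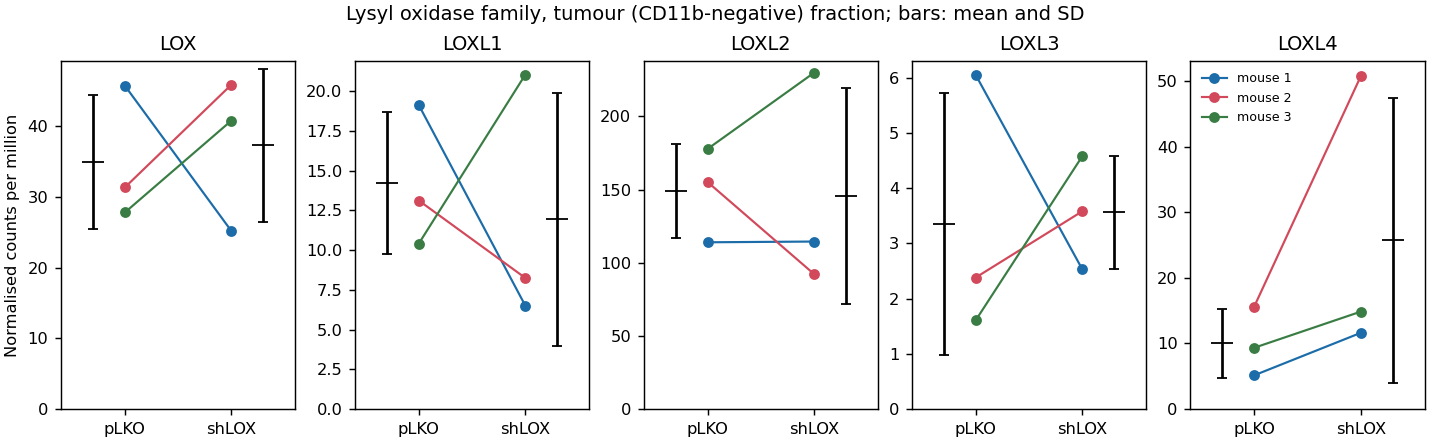
Normalised CPM (y axis) of the 5 lysyl oxidase genes in the tumour libraries, by vector (x axis); lines join the libraries of a mouse, and bars beside them give the mean and SD of 3. LOX was at 45.7 and 25.2 CPM in mouse 1 and was higher in the libraries labelled shLOX in mice 2 and 3, and LOXL4 was higher there in all 3 mice.

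The next comparison asked which tumour-cell genes differed between the pLKO and shLOX tumours. As the number of transduced lines is not given, differences between lines cannot be told apart from those between vectors. The p-values cover the spread between tumours only. Of 27172 genes tested, 18 passed the threshold, 8 higher and 10 lower in the libraries labelled shLOX, and all 18 had the same sign in 3 of 3 mice. Of the genes that rose, ANGPTL4, a secreted inhibitor of lipoprotein lipase (ENSG00000167772, chromosome 19, 8363289 to 8374373), went from 2.44 ± 0.274 to 73.2 ± 59.8 CPM (log2 fold change 4.60, SE 0.42, edgeR adjusted p = 0.0141). MUC5B, a gel-forming secreted mucin (ENSG00000117983, chromosome 11, 1223066 to 1262172), rose from 14.6 ± 6.37 to 105 ± 98.8 CPM (2.54, SE 0.27, edgeR adjusted p = 0.0283). MUC5B stood at 48.3, 220 and 48.5 CPM in the shLOX libraries of mice 1, 2 and 3. In that of mouse 2, 68.0% of cells lay in a cluster led by MUC5B, which held 3.31 to 15.5% of the cells of the other 5 libraries; the cluster was looked at after seeing the data. PDLIM4, an actin-associated PDZ and LIM domain protein (ENSG00000131435, chromosome 5, 132257671 to 132273454), rose from 3.92 ± 0.304 to 30.1 ± 16.2 CPM (2.81, SE 0.32, edgeR adjusted p = 0.0379).

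Of the genes that fell, MAOB, a mitochondrial monoamine oxidase (ENSG00000069535, chromosome X, 43766611 to 43882447), went from 20.2 ± 6.71 CPM in pLKO to 0.268 ± 0.111 CPM (log2 fold change -6.17, SE 0.42, edgeR adjusted p = 0.00588). TBX3, a T-box transcription factor of mammary development (ENSG00000135111, chromosome 12, 114670254 to 114684164), fell from 30.7 ± 3.06 to 8.92 ± 2.01 CPM (-1.80, SE 0.20, edgeR adjusted p = 0.0327). Under a mean of 10 CPM, the neuronal adhesion gene NLGN4X (ENSG00000146938, chromosome X, 5840637 to 6228863) fell by 4.07 on the log2 scale, KHDC1 (ENSG00000135314, chromosome 6, 73241314 to 73310365) by 3.22 and the homeobox gene MSX1 (ENSG00000163132, chromosome 4, 4859666 to 4863936) by 4.43. Also at low level, QPCT, the glutaminyl cyclase that forms pyroglutamate (ENSG00000115828, chromosome 2, 37342827 to 37373322), rose by 3.56, and HS3ST3A1, a heparan sulfate sulfotransferase (ENSG00000153976, chromosome 17, 13495689 to 13601927), by 4.38. Of the 18, 7 had a mean of at least 10 CPM, and sizes ran from 1.80 to 6.68 on the log2 scale. The remaining 8, not taken by the rule for named genes and listed after their values were seen, were OLFM4, ZDHHC2 and LINC02188 among those higher, and KIF7, MKRN3, CCDC3 and the Ensembl genes ENSG00000236120 and ENSG00000238117 among those lower. ENSG00000238117 is annotated as antisense, and its reads were not told apart from those of the opposite strand.

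Without mouse 1 the count of 18 became 1, a gene among the 18. Without mouse 2 it became 2, of which 1 was among the 18. Without mouse 3 it became 300, which included all 18. Of the 27172 genes, 2368 had an unadjusted p under 0.05, a bound that a share of 0.05 passes by chance alone.

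**Figure D2:**
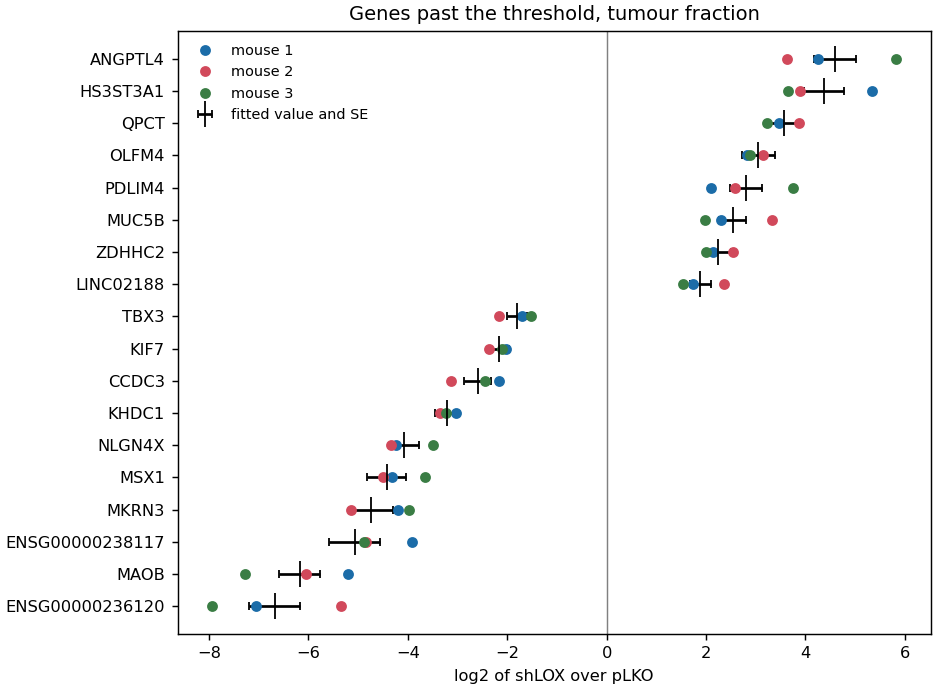
Log2 ratio of shLOX over pLKO (x axis) for the 18 genes past the threshold in the tumour fraction (y axis), with the fitted value and its SE in black and the value within each mouse as a coloured point. All 3 mice lie on the same side of 0 for each gene, from ENSG00000236120 at -6.68 to ANGPTL4 at 4.60.

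Gene lists were compared next, to see whether whole programmes differed between the pLKO and shLOX tumours. Of 33 human lists, 8 passed with the preset correlation, 4 towards higher and 4 towards lower values in the libraries labelled shLOX. None of the 8 passed with an estimated correlation, where each had an adjusted p = 0.884, and no member of these 8 lists passed singly over all genes. The estimated form rests on the few residual degrees of freedom of the fit, so little could pass whatever the correlation. For the ribosomal list, estimated at 0.012, the unadjusted camera p rose from 7.77e-08 to 0.0347. The 8 estimates ran from that value to 0.80, all above the preset 0.01, so neither form decides the calls. Cell division genes lay higher. In the list of G2 and M phase 50 of 52 members had positive fitted values, with a median log2 fold change of 0.38 (camera adjusted p = 1.59e-07, and adjusted p = 0.884 with an estimated correlation). Its leading members were the anaphase activator CDC20 at 0.97, the cytokinesis protein ANLN at 0.79 and GTSE1 at 0.58. Of the S phase genes 35 of 42 were positive, with a median of 0.20 (camera adjusted p = 0.00104, and adjusted p = 0.884 with an estimated correlation). Without mouse 2 the adjusted p of the S phase genes was 0.126. The transcription factor E2F8 stood at 1.12, the replication clamp PCNA at 0.54 and the replication factor CDC45 at 0.61. When adjusted over the list alone, 0 members of either list passed.

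Cholesterol synthesis genes also lay higher, with 22 of 23 positive and a median of 0.36 (camera adjusted p = 1.36e-05, and adjusted p = 0.884 with an estimated correlation). The decarboxylase MVD stood at 0.72 and the sterol reductase DHCR7 at 1.17, and 3 members passed when adjusted over the list alone. In the luminal programme 13 of 14 genes were positive, with a median of 0.41 (camera adjusted p = 0.00241, and adjusted p = 0.884 with an estimated correlation). The membrane mucin MUC1 stood at 1.06 and the simple-epithelium keratins KRT8 and KRT7 at 0.82 and 0.75, and 4 members passed when adjusted over the list alone. The medians of this list in mice 1, 2 and 3 were 0.65, 0.42 and 0.08, and KRT8 was at 141, 326 and 145 CPM in the shLOX libraries, highest in the one rich in MUC5B-led cells. Without mouse 1 its adjusted p was 0.152 and without mouse 2 0.0574. Cytoplasmic ribosomal protein genes lay lower, with 48 of 52 negative and a median of -0.22 (camera adjusted p = 1.28e-06, and adjusted p = 0.884 with an estimated correlation). RPS24 stood at -0.89 and RPL23 and RPL34 at -0.57 each, and 0 members passed when adjusted over the list alone. Processed pseudogenes copy many ribosomal protein genes closely, so how reads were divided between them is uncertain.

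Matrix genes lay lower in mice 1 and 2. Of the fibroblast markers 13 of 14 had negative fitted values, with a median of -0.63 (camera adjusted p = 0.00184, and adjusted p = 0.884 with an estimated correlation). The matricellular protein POSTN stood at -0.90, the collagen VI chain COL6A3 at -1.48 and the matrix glycoprotein FBLN1 at -0.71, and 2 members passed when adjusted over the list alone. Collagens and matrix glycoproteins had 21 of 27 negative values and a median of -0.42 (camera adjusted p = 0.00363, and adjusted p = 0.884 with an estimated correlation). Apart from POSTN, which is in both lists, COL6A2 stood at -1.76 and THBS1, a secreted activator of TGF-beta, against the list's direction at 0.88; adjusted over the list alone, 1 member passed upward and 4 downward. Matrix proteases and inhibitors had 20 of 27 negative values and a median of -0.33 (camera adjusted p = 0.0183, and adjusted p = 0.884 with an estimated correlation). The collagenases MMP13 and MMP1 stood at -1.36 and -1.52 and matrilysin MMP7 at 2.20, with 4 members up and 4 down when adjusted over the list alone.

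In mouse 3 the medians of the fibroblast markers, of the collagens and of the proteases were 0.48, 0.62 and 0.02, against -1.77, -0.79 and -0.50 in mouse 1. Without mouse 1 only 5 of 33 lists passed and without mouse 3 it was 14, and without mouse 1 the adjusted p of these 3 lists became 0.867, 0.296 and 0.188; without mouse 2 that of the collagens was 0.0700. The share of fibroblast-like cells moved with these lists, at 31.5% in the pLKO library of mouse 1 and 4.55% in its partner. Without the collagen-led cells the adjusted p of the fibroblast markers was 0.0214, that of the collagens 0.0279 and that of the proteases 0.0758, so the last no longer passed.

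**Figure D3:**
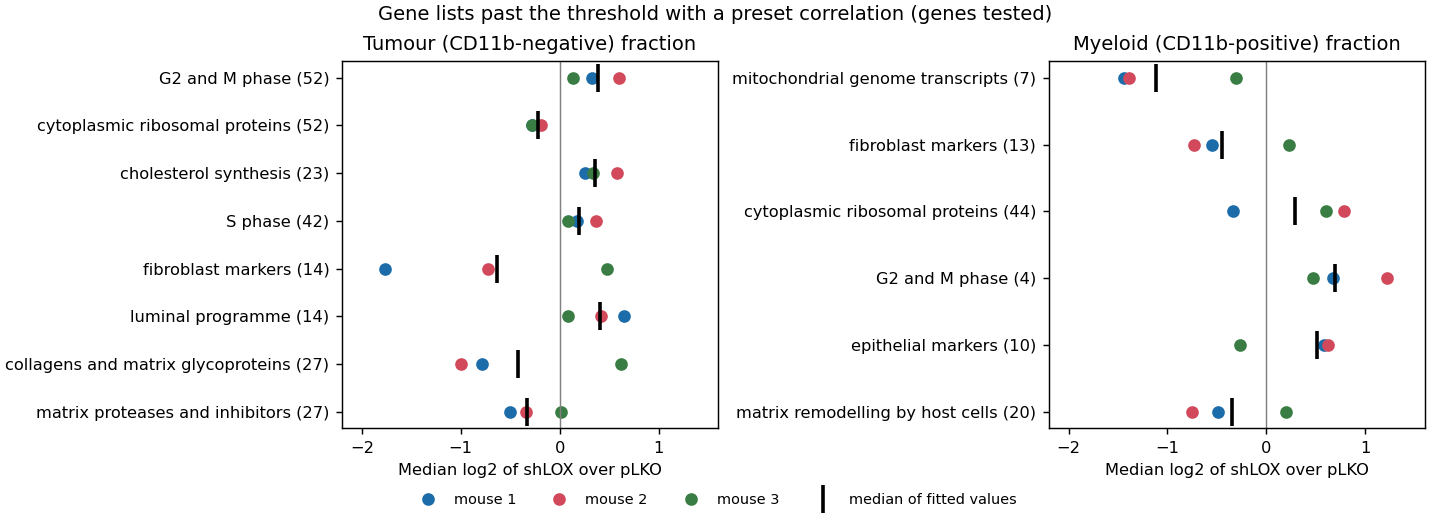
Median log2 ratio of shLOX over pLKO (x axis) of the lists past the threshold with a preset correlation (y axis, genes tested in brackets), for the tumour fraction on the left and the myeloid fraction on the right; points are the medians within each mouse and bars the median of the fitted values. Fibroblast markers reached -1.77 in mouse 1 and 0.48 in mouse 3 of the tumour fraction, and mitochondrial transcripts of the myeloid fraction lay below 0 in all 3 mice.

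The share of tumour cells in S or G2/M phase, called from the S and G2/M genes in cells thinned to 3400 UMIs, was 34.1 ± 3.70% in pLKO and 41.1 ± 7.16% in the libraries labelled shLOX (SD, n = 3 each). It was higher in 3 of 3 mice, at 38.3, 31.6 and 32.3% against 49.1, 39.0 and 35.3%, a mean difference of 7.06 points (SD 3.91, exact sign-flip permutation test, two-sided, p = 0.25, the smallest that 3 mice allow). G2/M cells made up 12.9% and 17.7% and S cells 21.2% and 23.4%. The S difference of 2.21 points was 0.24 without mouse 1, and without thinning it was positive in only 2 of 3 mice; without the collagen-led cells as well as mouse 1 it was -0.34 points. Thinning left out 212, 539 and 465 cells of the pLKO libraries and 310, 0 and 922 of the others; without thinning the difference was 6.58 points. Free RNA from dividing cells can enter such phase calls, and its level was not measured.

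Fibroblast-like cells, led by collagen genes such as COL1A1, made up 15.6 ± 13.9% of the pLKO tumour libraries and 6.25 ± 5.73% of those labelled shLOX (SD, n = 3 each). By mouse they were 31.5% (95% Wilson interval 29.9 to 33.2), 6.49% (5.64 to 7.46) and 8.67% (7.92 to 9.49) against 4.55% (3.92 to 5.28), 1.56% (1.25 to 1.94) and 12.6% (11.7 to 13.6). The mean difference was -9.32 points, with a lower share in mice 1 and 2 and a higher one in mouse 3 (exact sign-flip permutation test, two-sided, p = 0.5). Without mouse 1 it was -0.49 points and without mouse 3 -16.0 points. The shares depended on the clustering, at 26.1% and 14.4% with a Leiden resolution of 1, and in filtered cells the libraries labelled shLOX held 15.0%, a difference of -14.0 points. Most of the class, 2109 cells, lay in a cluster with the basal keratin genes KRT5, KRT14 and KRT17 at 148, 113 and 196 CPM and 9 fibroblast markers detected. Of the fibroblast markers PDGFRA stood at 34.4 CPM there, against 0.835 to 7.30 in the clusters without a name, and FBLN1 at 39.0 against 1.67 to 11.2, while DCN and LUM were at 0.776 and 0.806 CPM against at most 0.230 and 0.167. Intervals cover counting error only.

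**Figure D4:**
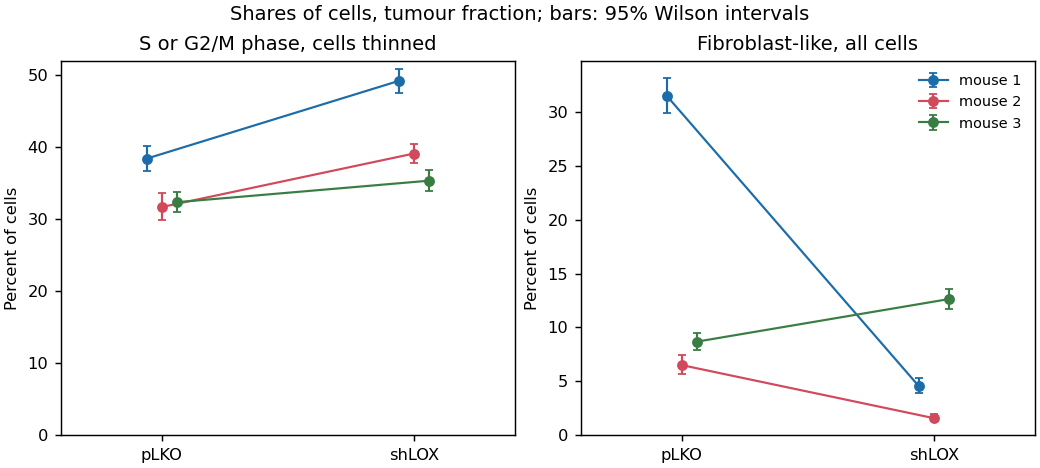
Percent of tumour-fraction cells (y axis) in S or G2/M phase (left, cells thinned to 3400 UMIs) and called fibroblast-like (right), by vector (x axis); points are libraries with 95% Wilson intervals, and lines join the libraries of a mouse. The cycling share was higher in the library labelled shLOX of each mouse, and the fibroblast-like share reached 31.5% in the pLKO library of mouse 1.

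In the CD11b-positive fraction the comparison asked how host cells around the 2 kinds of tumour differed, again by label, as LOX was not lower in the tumour cells labelled shLOX. No mouse gene passed: edgeR called 0 of 5239 genes, DESeq2 called 2 and 313 had an unadjusted p under 0.05. The genes with the smallest p and the same sign in 3 of 3 mice are given as values only. Flnc, an actin cross-linking filamin, stood at 78.6 ± 31.0 CPM in pLKO and 22.4 ± 13.8 CPM in shLOX (log2 fold change -1.94, SE 0.26, edgeR adjusted p = 0.406). The transcription factor gene Nfatc2 (-1.34), Dpp6 (-2.01), the potassium channel gene Kcnma1 (-1.45) and Lrrn4cl (-1.53) were the others on the negative side. On the positive side were the keratin genes Krt42 (1.89) and Krt19 (2.29), Eny2 (1.33), the chromatin protein gene Hmgb2 (1.25) and the ion transporter gene Slc12a2 (1.25). Apart from Flnc, each of these had an edgeR adjusted p of 0.797.

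Host lysyl oxidases had negative fitted values, Lox at -0.36 (SE 0.43), Loxl1 at -0.48, Loxl2 at -0.33 and Loxl3 at -0.49, with edgeR adjusted p from 0.799 to 0.884. Each of the 4 was higher in shLOX in mouse 3 and lower in mice 1 and 2, and Loxl4 was too low to be tested. Lox was at 74.3, 39.2 and 73.2 CPM in pLKO and at 37.2, 17.8 and 147 CPM in shLOX. The family as a list did not pass (camera adjusted p = 0.167). Without mouse 3 it passed towards lower values at the preset correlation, with a camera adjusted p of 0.00231. In the fit of all mice its estimated correlation was 0.958, far above the preset 0.01. No estimated correlation was used without mouse 3, so that call is weak evidence. Without mouse 2 the fitted values of Lox, Loxl2 and Loxl3 were 0.01, 0.06 and 0.11, and without mouse 3 37 mouse genes passed in place of 0.

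Of 26 mouse lists tested, 6 passed with the preset correlation, 3 in each direction. None passed with an estimated correlation, where each of the 6 had an adjusted p = 0.831, and no member passed singly over all genes. As in the tumour fraction, few residual degrees of freedom leave the estimated form little power. The estimates for the 6 lists ran from 0.15 to 0.92, far above the preset, so neither form decides the calls. Transcripts of the mitochondrial genome had the smallest p, with 7 of 7 members negative and a median of -1.12 (camera adjusted p = 1.04e-06, and adjusted p = 0.831 with an estimated correlation). Of these respiratory chain genes mt-Nd1 stood at -1.29, mt-Nd5 at -0.94 and mt-Cytb at -1.21, and 6 passed when adjusted over the list alone. The mitochondrial share of counts was 4.15 ± 1.37% in pLKO and 2.39 ± 1.01% in shLOX, lower in 3 of 3 mice (SD, n = 3 each, exact sign-flip permutation test, p = 0.25). Fibroblast markers had 13 of 13 negative values and a median of -0.45 (camera adjusted p = 0.000353, and adjusted p = 0.831 with an estimated correlation). The receptor gene Pdgfrb stood at -0.81, Pi16 at -0.82 and the proteoglycan gene Dcn at -0.48, with 0 passing when adjusted over the list alone; in mouse 3 the median was 0.23, and without mouse 2 the adjusted p was 0.0705. Matrix remodelling genes had 13 of 20 negative values and a median of -0.35 (camera adjusted p = 0.0407, and adjusted p = 0.831 with an estimated correlation). The matrix metalloproteinase genes Mmp2, Mmp13 and Mmp9 stood at -0.64, -1.06 and -1.06, with 0 passing when adjusted over the list alone; in mouse 3 the median was 0.20. The adjusted p of this list was 0.0898 without the mouse term, 0.0570 with thinned counts, 0.0721 in the sublibraries sequenced once and 0.120 without the 5% of cells with the most UMIs, and 0.147 and 0.483 without mice 1 and 2.

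On the positive side, cytoplasmic ribosomal protein genes had 33 of 44 positive values and a median of 0.29 (camera adjusted p = 0.0019, and adjusted p = 0.831 with an estimated correlation). Rps25 stood at 0.86, Rpl24 at 0.66 and Rpl14 at 0.76, with 0 passing when adjusted over the list alone; in mouse 1 the median was -0.34, and the adjusted p was 0.498 without mouse 2 and 0.264 without mouse 3. All 4 tested G2 and M phase genes were positive, with a median of 0.69 (camera adjusted p = 0.00626, and adjusted p = 0.831 with an estimated correlation). They included Hmgb2 at 1.25, the condensin gene Smc4 at 0.69 and the topoisomerase gene Top2a at 0.70, and 2 passed when adjusted over the list alone; without mouse 2 the adjusted p was 0.0673. Epithelial markers had 9 of 10 positive values and a median of 0.51 (camera adjusted p = 0.00654, and adjusted p = 0.831 with an estimated correlation). Of these the keratin genes Krt19 and Krt15 stood at 2.29 and 1.59, with 1 passing when adjusted over the list alone; in mouse 3 the median was -0.27. The adjusted p of this list was 0.121 without mouse 1 and 0.185 without the 5% of cells with the most UMIs. The cluster with the highest median UMIs (2007 barcodes, median 1809) had genes named as pseudogenes among its leading ones, such as Ptma-ps2 and Rpl17-ps1. Human tumour reads counted on the mouse reference are therefore a candidate source for the epithelial, ribosomal and G2 and M phase values. Such reads could also leave a smaller share of counts to host genes, and so lower the negative lists and the host lysyl oxidases. By mouse the medians were 0.58, 0.62 and -0.27 for epithelial markers and -0.54, -0.73 and 0.23 for fibroblast markers. The mitochondrial medians did not turn in mouse 3. Neither part was tested. Without mouse 3 the count of lists was 12 in place of 6. Of the 96 leading genes of mice 1 and 2, 29.2% had the same sign in mouse 3. Without that mouse 5 of the 6 lists still passed, and the mitochondrial and G2 and M phase lists had medians of the same sign in 3 of 3 mice.

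Few genes took most counts in this fraction. The 9 most abundant genes, led by the ribosomal RNA sequence Rn18s-rs5 and by Cdk8, took 79.8 to 88.2% of the counts of a library (95% Wilson intervals 79.8 to 79.9 and 88.1 to 88.2 at the ends). Rn18s-rs5 took 38.2 to 61.5% and Cdk8 6.97 to 37.5%. Without those 9 genes edgeR again called 0 genes, of 5679 tested, with 328 at an unadjusted p under 0.05.

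**Figure D5:**
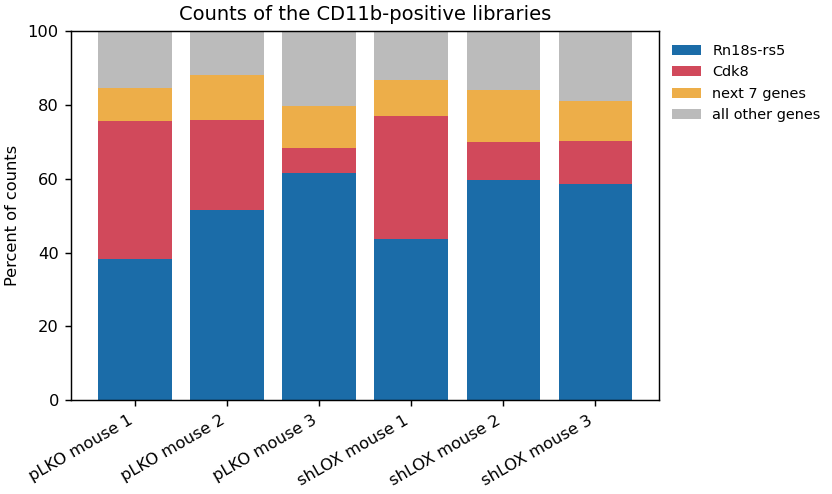
Percent of the counts of each CD11b-positive library (y axis) taken by Rn18s-rs5, by Cdk8, by the next 7 most abundant genes and by all others, for each library (x axis). Cdk8 took 37.5% in the pLKO library of mouse 1 and 6.97% in that of mouse 3.

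No cluster of the CD11b-positive cells could be named macrophage-like from its markers, so no share of macrophages is given. Endothelial-like cells, with genes such as Flt1 and Pecam1, made up 2.14 ± 0.291% in pLKO and 2.75 ± 1.70% in shLOX, and fibroblast-like cells 12.2 ± 8.54% and 11.4 ± 3.42% (SD, n = 3 each). With a Leiden resolution of 1 the fibroblast-like shares were 25.0% and 24.1%. The differences of 0.61 and -0.74 points had opposite signs in different mice (exact sign-flip permutation test, two-sided, p = 0.75 for each, and 0.75 adjusted over both classes). Without mouse 1 they were -0.014 and 2.79 points, and without mouse 3 1.76 and -4.87 points. The endothelial markers as a list lay the other way, with 8 of 9 negative and a median log2 fold change of -0.41 (camera adjusted p = 0.0542). Their medians in mice 1, 2 and 3 were -0.08, -0.16 and -0.92. A cluster of 456 barcodes whose best markers were those of neutrophils, but with none among its leading genes, made up 1.85 ± 0.649% in pLKO and 6.95 ± 6.62% in shLOX and was higher in 2 of 3 mice, a mean difference of 5.10 points that was 1.53 without mouse 2. At a Leiden resolution of 1 a cluster of 606 barcodes with macrophage markers, likewise unnamed, made up 2.77 ± 0.707% and 7.88 ± 6.19% and was higher in 3 of 3 mice, a mean difference of 5.11 points that was 1.71 without mouse 2. Both unnamed clusters were picked out after seeing the data. Their leading genes were largely the same, Pik3ap1, Srgn and Lilrb4b among them. They are therefore not separate results, and which leukocytes they hold stays unsettled. The bead separation and the depth gap between libraries can set these shares.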

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

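The test of pseudogene reads in collagen-led cells and the test of an exchange in mouse 3 were chosen only after the result was seen, as was the removal of collagen-led cells.

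The CD11b-negative matrices, meant to hold human tumour cells, contained 389 barcodes in a low-UMI cluster led by collagen genes, and no comparison of the report concerns that cluster alone. They were picked out as signal outside the main measurement. COL1A1 reached 47165 CPM there against 35.8 to 6286 CPM in the other clusters, KRT5 stood at 42.0 CPM against 95.8 to 276, and the median was 2612 UMIs. Host mouse fibroblasts read on the human reference are a candidate source, as mouse reads often match processed pseudogenes: annotated pseudogenes took 4.16 to 5.49 times the share of counts that they took in the clusters without collagen lead, in 6 of 6 libraries. The beads removed only CD11b-positive cells and would not have removed fibroblasts. All 14 fibroblast markers passed the filter on low counts in the tumour fraction, but so did 12 of 13 endothelial markers. Passing that filter therefore does not bear on the source. The larger collagen-led cluster of 2109 cells had pseudogene shares of 0.466 to 0.519%, against 0.347 to 0.379% in the clusters without collagen lead, and whether it holds tumour cells with mesenchymal genes stays open and was not tested.

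The CD11b-positive matrices contained 313 endothelial-like barcodes, cells that CD11b beads should leave behind, which were picked out in the same way. Flt1 stood at 655 CPM and Pecam1 at 501 CPM in them.

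LOX transcript was not lower in the tumour libraries labelled shLOX. Host cells counted as human LOX would have to hide a fall. Without both collagen-led clusters, which held 46.5% of LOX counts in 1 pLKO library, the fitted log2 fold change was 0.22 (SE 0.22). The clusters kept held 98.2, 99.2 and 89.2% of LOX counts in the shLOX libraries of mice 1, 2 and 3. The refit could therefore hardly have shown a fall. The removed cells held too few LOX counts there to hide a large one. These shares, and not the refit, argue against the cells of those clusters as the source. The clusters kept still held 76.8, 89.0 and 62.8% of COL1A1, COL1A2 and COL3A1 counts in the shLOX libraries of mice 1, 2 and 3. Whether those are host reads was not tested, so host reads in the kept clusters stay open. An exchange of the labels of the tumours in 1 mouse is argued against by 20 genes at least 4-fold different in each mouse, all with 3 mice alike and 0 with any mouse apart. That count was taken after 2 others had decided nothing: of the 100 leading genes of the other mice 58.0% had the same sign in mouse 3, between the bounds of 40 and 60% set beforehand, and of 103 genes called without mouse 3 at 4-fold or more it was 64.1% (95% Wilson interval 54.5 to 72.7). Loss of the shRNA's effect by week 7, a knockdown seen in protein rather than transcript, or one that never took hold remain open and were not tested.

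A few genes, led by Rn18s-rs5 and Cdk8, took most counts of the CD11b-positive libraries. Human reads counted on the mouse reference are argued against as the whole source, because the 9 genes also took at least 63.1% of counts in the cells named fibroblast-like or endothelial-like in each library, over the 50% set beforehand. In each library the share was higher in the other cells, at 82.3 to 90.4%, which is the direction such reads would give, so a part from them stays open. Broken cells with few counts cannot be told apart from other sources: the share of the 9 genes in the 25% of barcodes with the fewest counts minus that in the 25% with the most ran from -14.9 to 0.925 points, and 1 library was above 0. No biological explanation was tested, as the pattern was in both groups.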

How the results depend on the processing

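The removal of collagen-led cells, of the 5% of cells with the most UMIs and of the 9 most abundant genes was chosen after seeing the data; all other alternatives were planned. Leaving out cells by Scrublet was not run because the caller did not work, and the share of macrophage-like cells has no value.

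The 18 tumour genes became 720 without the filter on low counts, where the median fold change of all genes was 0.08, 337 by DESeq2's Wald test, 30 without both collagen-led clusters and from 1 to 300 with a mouse left out. Leaving a mouse out also leaves fewer samples; otherwise the cause was not tested. Without the replicate block 20 genes passed, 14 of them among the 18, with 6 up and 14 down in place of 8 up and 10 down. The other 7 alternatives gave 13 to 20 genes, and all 18 kept their sign in every alternative. The 8 tumour lists became 0 with an estimated correlation, 0 by fry and from 5 to 14 with a mouse left out, which kept 4, 5 and 8 of the 8 without mice 1, 2 and 3. In the sublibraries sequenced once 7 lists passed, all among the 8. Without both collagen-led clusters 8 passed, 7 of them among the 8. The count of 0 myeloid genes became 23 without the filter, where the median fold change of all genes was 0.12, 2 by the Wald test and 0 to 37 with a mouse left out. The 6 myeloid lists became 0 with an estimated correlation, 0 by fry, 5 to 12 with a mouse left out and 5 without the block. Without mice 1, 2 and 3 only 4, 2 and 5 of the 6 were kept, and without the 5% of cells with the most UMIs 4 lists passed. The block changed no other count by over 1.5 times.

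Some directions turned. LOX ran from -0.16 to 0.55 with a mouse left out, LOXL1 from -1.12 to 0.18, LOXL2 from -0.37 to 0.18 and LOXL3 from -0.35 to 1.05. Host Lox was 0.076 without the block and ran from -1.05 to 0.011 with a mouse left out, Loxl2 from -0.93 to 0.057 and Loxl3 from -1.15 to 0.11, with Loxl3 at 0.017 in the re-sequenced sublibraries. The endothelial-like share difference ran from -0.014 to 1.76 points and the fibroblast-like one of the myeloid fraction from -4.87 to 2.79 points, and the latter was 1.06 in filtered cells; the cause was not tested. The cycling difference kept its sign throughout, from 5.20 to 9.10 points in all thinned cells with a mouse left out. It was 4.00 points without the collagen-led cells and mouse 1, and 12.6 points in filtered cells without mouse 3. Of 518 values of the 37 named tumour genes other than LOX under alternatives, 454 kept their direction and side of the threshold, 26 lost the call, 35 gained one and 3 turned (LOX itself turned without mouse 2 and without mouse 3); of 378 of the 30 named mouse genes it was 354, 0, 19 and 5. The shallow myeloid libraries, in which 9 genes took most counts, left 5239 genes testable against 27172.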

Other observations

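The counts by fold size and the sign counts by mouse were chosen only after the result was seen; the splits were planned.

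Several other programmes, among them hypoxia, inflammation and energy metabolism, gave no call in the main fit of the tumour cells. Under some alternatives more lists passed, such as 14 without mouse 3 and 10 without the 5% of cells with the most UMIs. Hypoxia genes had 19 of 25 negative values (median log2 fold change -0.23, camera adjusted p = 0.0657), although ANGPTL4, a hypoxia-induced member, was among the genes that rose. Genes of the epithelial-mesenchymal transition (median -0.16) and NF-kB targets (median -0.27) had the same adjusted p, 0.0657, and their medians in mouse 3 were positive at 0.16 and 0.44. Glycolysis genes had a median of 0.16 and nuclear oxidative phosphorylation genes one of -0.09 (camera adjusted p = 0.0989 and 0.0918). Interferon response, integrin and focal adhesion genes and basement membrane laminins lay near 0 (adjusted p = 0.977, 0.839 and 0.977), the first and second with median and mean of opposite sign. The basal keratin programme had 8 of 15 positive values, 1 passing upward and 1 downward when adjusted over the list alone (camera adjusted p = 0.835).

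In the CD11b-positive fraction 5 of 14 macrophage markers were counted well enough to be tested, with a median of -0.40 and medians by mouse of -0.85, -0.92 and 1.24 (camera adjusted p = 0.282). Chemokines and their receptors had a median of -0.47, with -0.78, -0.80 and 0.86 by mouse (adjusted p = 0.143), and inflammatory macrophage genes one of 0.03, with -0.10, -0.62 and 1.01 (adjusted p = 0.581). Leaving out a mouse gave calls for these lists: without mouse 3 the adjusted p was 0.000366 for the chemokines and 0.0290 for the macrophage markers, and without mouse 2 it was 0.0434 for the inflammatory macrophage genes. Hypoxia genes of host cells had 13 of 17 positive values and a median of 0.14 (adjusted p = 0.143).

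Among 17763 tumour genes with a mean of at least 1 CPM, 58 differed at least 2-fold in each mouse in the same direction, 24 up and 34 down. With mouse 1, 2 or 3 apart from the others there were 8, 9 and 23. At 4-fold there were 20 alike and 0 with a mouse apart, and at 8-fold 8 and 0. In the myeloid fraction, at 2-fold, 7 of 5239 genes were alike in 3 mice, and 1, 0 and 42 had mouse 1, 2 or 3 apart. Mouse 3 was the one whose tumours differed least in volume, at 283 and 247 mm3.

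The 6 libraries of a fraction can be split in 10 ways, too few for a share under 0.05. Each split was fitted with the mouse term, and only 4 splits, the real one included, part all 3 pairs. In the rest the group difference rests on 1 mouse, so few genes could pass. They also come in pairs that are the same fit with the sign turned, and no rank among all 10 is read. In the tumour fraction the real split called 18 genes and each of the others that part all 3 pairs called 0. For tumour lists the real split called 8 and those others 16, 4 and 9. In the myeloid fraction the real split called 0 genes, a count that no split can fall below, and those others 69, 0 and 0. For myeloid lists the real split called 6 and those others 17, 3 and 3. The split that called 69 genes and 17 lists set the pLKO libraries of mice 1 and 2 and the shLOX library of mouse 3 against the rest, as did the one with 16 tumour lists. It parts all 3 pairs, as 4 of the splits do, and points to a structure of the myeloid libraries in which mouse 3 is turned against mice 1 and 2. Of the 87, 89 and 96 leading myeloid genes of the other mice, 67.8, 74.2 and 29.2% had the same sign in mouse 1, 2 and 3 when it was left out. The deeper library was the one labelled shLOX in mice 1 and 2 and the one labelled pLKO in mouse 3, so depth follows the same split; the tumour libraries had the same order of depth. Recorded input cells turned in mouse 3 as well. For mice 1, 2 and 3 the myeloid ones were 368000, 290000 and 38000 in pLKO and 156000, 52000 and 108000 in shLOX. Those of the tumour fraction were also higher in pLKO in mice 1 and 2 and lower in mouse 3. Exchanged labels of the CD11b-positive libraries of mouse 3 stay open and were not tested. Some measures ran in mouse 3 as in the others. The mitochondrial share was 5.68% in pLKO and 3.53% in shLOX, and the medians of the mitochondrial and G2 and M phase lists were -0.31 and 0.47. Both lists were called with mouse 3 in the fit, and other lists, such as the fibroblast markers, turned in it. At 2-fold, 42 genes had mouse 3 apart and 7 had all mice alike. These measures therefore do not decide for or against an exchange.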
